A study of Mus musculus with 48 samples.

How the data were processed

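Ultra-low-input ribosome profiling, which reads the mRNA fragments that ribosomes shield from nuclease, was carried out on sorted mouse bone marrow cells, 160 cells per library. The labels give 12 groups with 4 runs each, 48 runs in all: T, B, myeloid and erythroid cells, MEP (megakaryocyte-erythroid progenitors), GMP (granulocyte-macrophage progenitors), CMP (common myeloid progenitors), CLP (common lymphoid progenitors), LT-HSC (long-term hematopoietic stem cells), MPP (multipotent progenitors), and WT and Mat-KO HSC. No RNA-seq of the same cells was used here, so a footprint level combines the amount of an mRNA with how much it is translated, and no translation efficiency was computed. Per the submitters' processing notes, reads were trimmed with Trimmomatic and aligned to mm10 with STAR 2.7.3a. The deposited values are raw counts of footprints per gene, in whole numbers. Runs 1 and 2, which share one title prefix, list 15150 genes, and runs 3 and 4, which share the other, list 54232 features. Per the file headers, the latter were made with repeats and duplicates removed. The 15125 genes in both were used, and 23 symbols that a spreadsheet had turned into dates were restored from their gene identifiers.

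The runs were compared before any test between groups. A chi-square test of gene counts, over genes with 20 or more counts, gave a median ratio of chi-square to degrees of freedom of 0.457 between runs 1 and 2 and 0.458 between runs 3 and 4. Between these pairs of runs it was 5.39 to 7.27. The rule fixed before the data were examined sets a limit of 1.5 in at least 10 of the 12 groups, so it would have taken runs 1 and 2 as one sample and runs 3 and 4 as another. The submitters also state 2 biological replicates per group, each with 2 technical ones, and no label says which runs belong to which. The values reported follow neither. A check added after the data were seen removed a factor per gene that is common to all 12 groups, over genes with 20 or more counts in every group. As a mean over genes, the ratio was then between 1.17 and 1.28, against 0.455 and 0.456 within the pairs. The ratio between pairs thus stayed above that within them. Between the summed pairs it was 1.83 to 2.27 by level of the gene. Independent counts would give 1, and the runs of a pair lay under it, so they are not independent draws. Summing such runs can by itself raise the ratio, so the size of the remaining difference cannot be read from 1.83 to 2.27. Such a factor takes up any difference between the pairs that all groups share, whatever its cause. On the fall of the ratio, the 4 runs of each group were nonetheless summed and counted as 1 sample per group. Fits that take the pairs of runs as 2 replicates, or the runs as 4, were run as alternatives. Summed counts ranged from 982124 in Mat-KO HSC to 6024938 in CLP.

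Levels (CPM) were computed on TMM-scaled library sizes from edgeR 4.0.16 in R 4.3.3. Summing the runs leaves a comparison of 2 libraries without a test, and fits on the pairs of runs are given beside it as counts. The comparison is given as a ratio of CPM with an exact conditional binomial (Clopper-Pearson) 95% interval, on counts divided by 1.87, the ratio of variance to mean between the pairs of runs once the factor per gene was removed. PCR reads without molecular identifiers are not independent molecules, and the intervals and floors cover counting error only. A gene was counted as different when the higher library had at least 50 CPM and 50 counts, the ratio was at least 2-fold and the interval excluded 1. Where one library had 0 counts, the lower end of the interval is given. Against a median at or under the level of 3 counts, the fold is a lower bound over that level. In data simulated at the depths of the WT and Mat-KO libraries (3 draws), this count found 100 of 100 genes changed 4-fold, 54.3 of 100 changed 2-fold and 9 of the unchanged genes, among 4259 eligible genes, and the intervals held the true ratio for 95.3% of them. The simulated noise had the same ratio of variance to mean, 1.87, that the intervals assume. This coverage therefore checks the computation and not that assumption.

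The 6 stem and progenitor populations were tested against the 4 mature ones with edgeR quasi-likelihood (filterByExpr, TMM), 1 library per population and an adjusted p (Benjamini-Hochberg) under 0.05. On simulated data at this size it found 72.3 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, with 19 false calls. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one (limma 3.58.1). The share of counts in each list was compared by a two-sided exact permutation test over the 10 populations, whose smallest possible p is 0.0047619. In comparisons of 2 libraries, a list's median log2 ratio, with 1 CPM added to both levels, was placed among those of 10000 random lists matched on level, as a description. For the lists named with members at 0, the median with these set to their floor is also given where it differs. Each population was also set against the median of the other 9, with exact Poisson intervals on its own counts, and similarity was the correlation across genes of log2 of CPM plus 1. DESeq2 1.42.0 gave size factors and a Wald test as alternatives, and Python 3.11.15 with scipy 1.17.1 the rest.

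The comparisons, the 32 gene lists and the rule for the genes named were fixed before the data were examined. The rule names genes of the targeted locus and up to 4 members of a list that pass the test or, without one, have a mean of 50 CPM and an interval that excludes 1. It also names the 10 protein-coding genes with the largest rise and the 10 with the largest fall, at 20 CPM or more in the higher group (in comparisons of 2 libraries at 50 CPM and 50 counts or more, ranked by the interval bound nearest to no change, and only where all runs of equal number differ the same way), and the 5 highest for each population against the others. Not every gene the rule takes is named. Other genes are named only as examples, chosen after their values were seen, and are said to be so. Alternatives were other normalizations, other minimum levels, leaving out each run number or population, the runs of each title prefix alone, a replicate block, other tests and another reference library. Those added after the data were seen are libraries thinned to equal depth, totals without Lars2, the factor per gene, and the runs of each prefix alone for the lists.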

Results

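The series profiled ribosome footprints in 10 sorted hematopoietic populations of mouse bone marrow, and in HSCs with and without a maternally inherited deletion of the SNORD113-114 cluster, a set of small nucleolar RNAs in the imprinted Dlk1-Dio3 locus. The submitters state 2 biological replicates per group, each with 2 technical ones. The 4 runs of a group were instead summed into 1 sample. The chi-square ratio between the pairs of runs was 5.39 to 7.27. Once a factor per gene common to all groups was removed, it was, as a mean over genes, 1.17 to 1.28, against 0.455 and 0.456 within the pairs and 1.83 to 2.27 between the summed pairs. The choice rests on this fall and on immunoglobulin V genes shared by the pairs in 4 groups. Any difference between the pairs that all groups share would give the same fall, and the ratio between pairs stays above that within them. The runs of a pair are not independent draws, so summing them can by itself raise the ratio. By this choice n = 1 per group unless a number is given. The runs held 219693 to 3514299 counts each. Summed over the shared genes, the library labelled Mat-KO HSC held 982124 counts, WT HSC 2817921, LT-HSC 4220946, MPP 4413517, CMP 3869768, GMP 2359675, MEP 3071014, CLP 6024938, T cell 4659633, B cell 2984855, myeloid cell 2892596 and erythroid cell 5401341. Between 10895 and 13142 genes had a count in a library. Lars2, the mitochondrial leucyl-tRNA synthetase, took from 8.49% of the counts (CMP) to 19.01% (GMP). Whether these counts are footprints of its mRNA was not tested, and they are in the totals of the list shares below unless said otherwise.

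Lars2 was left out of the ranking of protein-coding genes used here. Among the others, neutrophil genes were among the highest in every library, whatever its label. S100a9 and S100a8, the subunits of calprotectin, and the granule genes Ngp, Ltf and Camp were among the 10 highest genes other than Lars2 in 12 of 12 libraries. S100a9 stood at 5172 CPM in the library labelled CLP and 15806 CPM in Mat-KO HSC. Lyz2, Actb and Myh9 were also among the 10 highest in all 12, and Mpo, the myeloperoxidase of early granulocytes, in 7. Of the 22 mature myeloid markers listed, 22 stood at 50 CPM or more in all 12 libraries, and they took 4.11% of counts in CLP and 7.85% in Mat-KO HSC.

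For the 9 lists that belong to a population, the markers were not highest in the library with that label. The 21 T cell markers took 0.00468% of counts in the library labelled T cell (95% interval 0.00387 to 0.00561) and 0.0122% in CLP, the highest share. Cd3e, a subunit of the T cell receptor complex, had 0 counts in the T cell library, whose 95% interval reaches 1.48 CPM, and 9.19 CPM in the erythroid cell library. The 18 B cell markers took 0.043% of counts in the library labelled B cell and 1.36% in CMP, where Ighm reached 8163 CPM and Igkc 4331 CPM. The 24 measured LT-HSC markers took 0.00888% in LT-HSC and 0.0252% in MEP, and GMP markers 0.977% in GMP and 1.49% in CMP. Erythroid markers took 0.451% in the erythroid cell library, second to 0.531% in the B cell library. Of the 9 lists that belong to a population, 0 were highest in the library of their own label, and by mean log2 level the mean rank of the own library was 4.89 among 10, against 5.5 by chance (permutation test of the labels, one-sided, 100000 permutations, p = 0.281). Megakaryocyte and platelet markers, not among these 9 lists, were highest in MEP, at 0.0528% of counts against 0.0232% in MPP. With 0 of the 9 lists highest in their own library, every comparison below names libraries by their labels, without assuming which cells they hold.

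**Figure D1:**
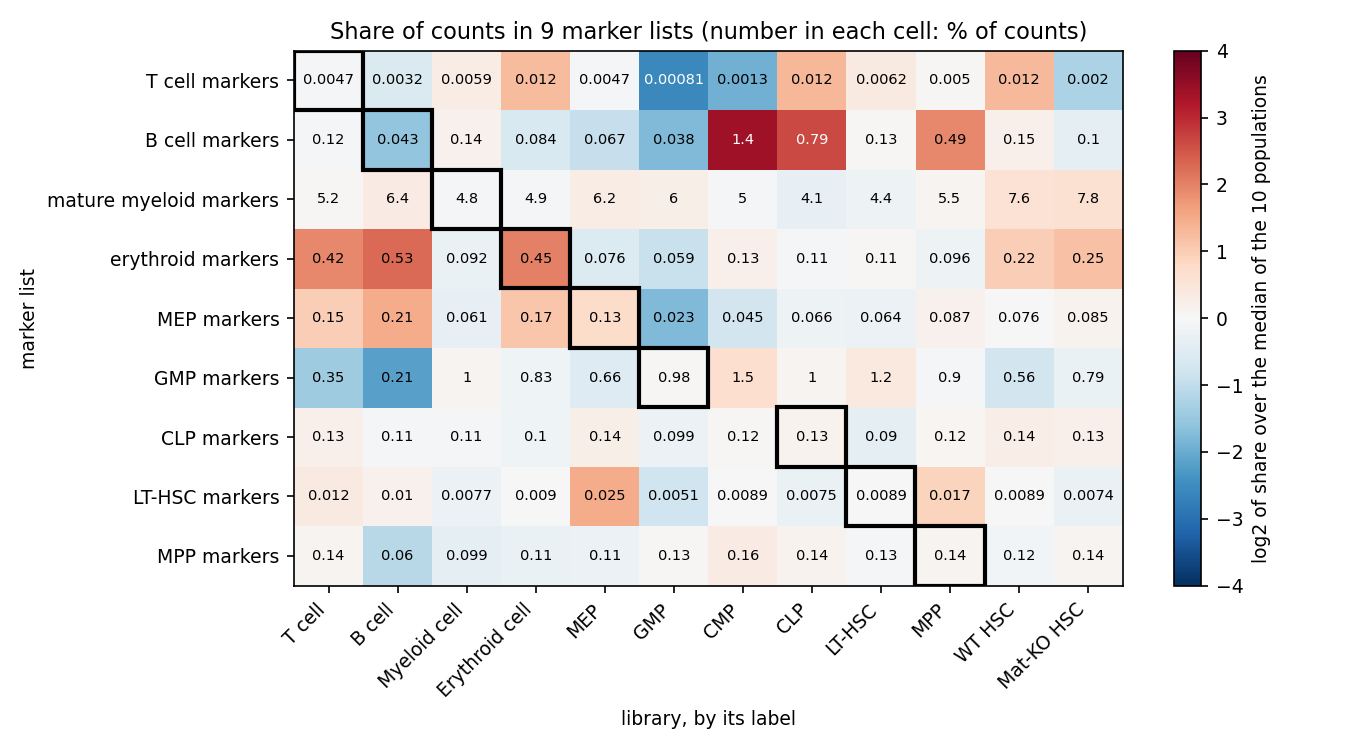
Percent of counts in 9 marker lists (vertical axis) in each of 12 libraries (horizontal axis), coloured by the log2 of the share over the median of the 10 populations, with the library of the list's own label outlined. B cell markers reach 1.36% in CMP and erythroid markers 0.531% in the B cell library, and 0 of the 9 outlined cells is the highest of its list.

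Genes of red cell maturation were lower in the 6 stem and progenitor libraries than in the 4 mature ones. Alas2, the first enzyme of erythroid heme synthesis, had a log2 ratio of -2.83 (SE 0.45, n = 6 and 4, adjusted p = 0.0217 by edgeR), from a mean of 66.9 CPM in the mature libraries to 9.08, and each of the 4 lay above each of the 6. The beta-globin gene Hbb-bs (-3.02), the erythroid nuclear protein Hemgn (-2.68), the transcription factor Sox6 (-2.63) and Slc4a1, the anion exchanger of the red cell membrane (-2.51), also fell, with edgeR adjusted p-values of 0.0217 to 0.0346. For these 4 genes the myeloid cell library lay within the range of the stem and progenitor libraries (Slc4a1 at 273 CPM, against 285 CPM in CMP and 867 CPM in T cell). Pkhd1l1 (-3.06), Scd1 (-2.80), a desaturase of fatty acids, Sec14l2 (-2.76) and Btnl10 (-2.65) were also among the largest falls. The other direction held 2 genes, Lyar, a nucleolar protein (1.21, SE 0.24, adjusted p = 0.0373 by edgeR), and Pdha1, a subunit of pyruvate dehydrogenase (0.71, SE 0.15, adjusted p = 0.0454 by edgeR), each higher in all 6 libraries than in any of the 4.

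In total 71 of 10787 genes passed by edgeR, 2 higher and 69 lower in stem and progenitor libraries, and 1061 had an unadjusted p under 0.05. The 2 groups did not overlap for 192 genes, 1.78% of those tested, where chance gives 0.952%. The count rests on single libraries: it was 0 without the T cell, the B cell or the erythroid cell library, 304 without myeloid cell, 3 without MEP or without CLP, 15 without LT-HSC, 28 without MPP, 29 without CMP and 35 without GMP. DESeq2's Wald test gave 203 genes, limma-voom 2 and library totals 27.

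**Figure D2:**
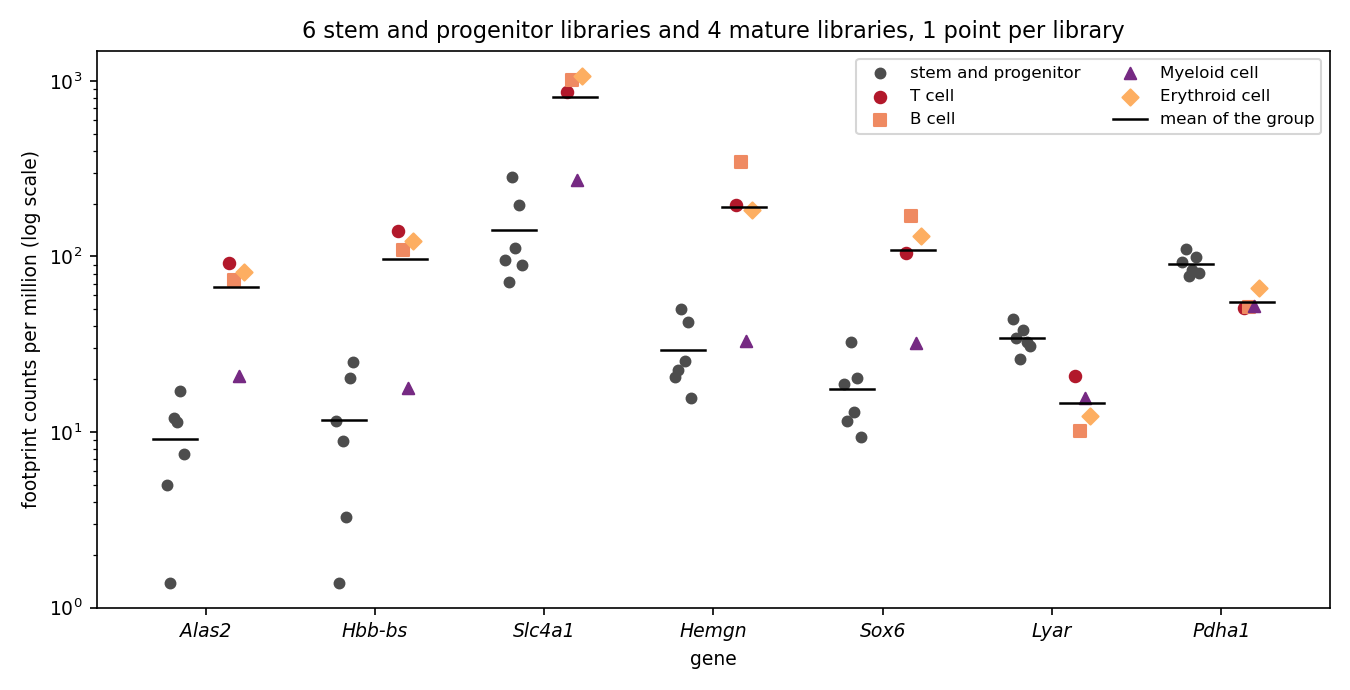
Footprint levels in CPM on a log axis for 7 genes, 1 point per library, with grey points for the 6 stem and progenitor libraries, coloured points for the 4 mature ones and bars for the means. For Alas2 the mature libraries lie above the others, with a mean of 66.9 CPM against 9.08, and for Lyar they lie below, at 14.7 CPM against 34.3.

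Of the 19 measured erythroid markers, 19 had a lower estimate in stem and progenitor libraries, 18 fell when adjusted over the list alone and 11 when adjusted over all genes (camera adjusted p = 2.1e-23, and adjusted p = 0.274 with an estimated correlation). Of 13 MEP markers, 12 had a lower estimate, 8 fell adjusted over the list alone and 2 over all genes, Rhd of the red cell blood group (-2.36) and Blvrb, a heme-degradation enzyme (-1.87), with a camera adjusted p of 7.3e-09 (adjusted p = 0.297 with an estimated correlation). GMP markers lay higher, with 14 of 16 estimates above 0 and 0 genes past the test (camera adjusted p = 7.3e-05, and adjusted p = 0.360 with an estimated correlation), as did glycolysis, with 13 of 15, 6 adjusted over the list alone and 0 over all genes (camera adjusted p = 0.000278, and adjusted p = 0.274 with an estimated correlation). With an estimated correlation 0 of the 29 lists passed. At the preset correlation alone, 7 further lists had camera adjusted p-values of 0.021 to 0.0356, against 0.274 to 0.563 with the estimated one, so their directions are not settled. By the preset one, MPP markers, plasma cell markers, mitochondrial ribosomal proteins, snoRNP proteins and the unfolded protein and integrated stress response pointed higher, and mature myeloid markers and cell cycle genes lower. As shares of counts, mature myeloid markers took 5.21% in stem and progenitor and 5.33% in mature libraries (two-sided exact permutation p = 0.833) and cell cycle genes 0.615% and 0.610% (exact p = 0.914). With library totals, at the preset correlation, 4 passed, the erythroid, MEP, GMP and glycolysis lists. The remaining 18 lists did not pass, among them large-subunit (adjusted p = 0.166) and small-subunit ribosomal proteins (0.263), initiation factors (0.387), elongation and termination factors (0.958), aminoacyl-tRNA synthetases (0.878), ribosome biogenesis factors (0.0604) and proteasome subunits (0.0604). NK cell markers, stromal and endothelial markers and the Dlk1-Dio3 genes had too few measured members.

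As shares of counts, glycolysis genes took a mean of 0.263% (SD 0.019, n = 6) in stem and progenitor libraries and 0.220% (SD 0.0165, n = 4) in mature ones (two-sided exact permutation p = 0.00952). The unfolded protein and integrated stress response took 0.290% (SD 0.034) and 0.228% (SD 0.0184; exact p = 0.00952), mitochondrial ribosomal proteins 0.149% and 0.124% (exact p = 0.0143), and small-subunit ribosomal proteins 0.400% and 0.355% (exact p = 0.0333). Erythroid markers took 0.0969% and 0.373% (exact p = 0.0238). MEP markers (exact p = 0.0429), plasma cell markers (0.0381) and proteasome subunits (0.0476) make 8 of 32 lists with an unadjusted exact p under 0.05, where 1.6 are due by chance, and 0 passed after adjustment over the 32, with 0.152 the smallest adjusted p. Without Lars2 in the totals, small-subunit ribosomal proteins had an exact p of 0.157 and proteasome subunits of 0.248.

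Against the median of the other 9 populations, several of the highest genes were shared between libraries of different labels. In the library labelled MEP, Vwf, the von Willebrand factor of megakaryocytes and platelets, stood at 336 CPM (95% interval 309 to 365), 65.8-fold above the median, beside Myom1 (64.6 CPM) and Mrvi1 (55.6 CPM), and Kcnj5 and Sdpr were at least 91.8-fold and 79.4-fold above it. The library labelled myeloid cell was highest for Prss34, a basophil protease, at 232 CPM (208 to 258; at least 328-fold), for the macrophage genes Cd5l (107 CPM) and Fcna (212 CPM), for Slco2b1 and for the B cell factor Pax5 (87.6 CPM). Prss34 also led LT-HSC (126 CPM) and CLP (66.9 CPM), and Jchain, which joins antibody chains in plasma cells, led CMP (244 CPM) and MPP (244 CPM). LT-HSC was further marked by Epx, the peroxidase of eosinophils, at 350 CPM, Pax5, H2-Eb1 and H2-Aa, and MPP by Synpo2, Ctsk, the collagen-degrading protease of osteoclasts (65.4 CPM), Src and Mmp14. In GMP the leading genes were less apart, with Tanc1 at 3.66-fold, Ccnd1, the cyclin D1 gene, at 3.08-fold, and Fam64a, Sgol2a and Il6st. CMP also had Chst1, Epx, Txndc5 and Ctsg, and CLP Jchain, Cplx2, H2-Eb1 and Dntt.

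The library labelled T cell was led by Dntt, the DNA polymerase of immature lymphocytes (142 CPM, 95% interval 127 to 157), the class II gene H2-Eb1 (261 CPM), Pkhd1l1, Hbb-bs and Alas2. The library labelled B cell was led by Ptprf (25.2-fold) and Apol8 (16.7-fold), with Hemgn (342 CPM) and Smim1 also among its highest, and erythroid cell by Pkhd1l1, with Dmtn, Epb42 and Hbb-bs. At least 2-fold above the median were 117 genes in T cell, 187 in B cell, 73 in myeloid cell, 112 in erythroid cell, 52 in MEP, 56 in GMP, 21 in CMP, 22 in CLP, 19 in LT-HSC and 49 in MPP, 708 in all. These ratios describe the 10 libraries and, with the runs summed, have no test. With the pairs of runs taken as 2 replicates, edgeR gave 693 such genes, and 725 with a replicate block.

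LT-HSC against MPP is the first step of the hierarchy. The class II genes H2-Eb1, H2-Aa and H2-Ab1 and their chaperone Cd74 were higher in the library labelled LT-HSC, by 24.99-fold (95% interval 16.8 to 38.7), 13.6-fold (10.3 to 18.3), 8.58-fold (6.78 to 10.996) and 4.79-fold (4.24 to 5.41). So were Prss34 (302-fold, 56.3 to 9690, against 2 counts), Epx (3.92-fold), Olfm4 of neutrophils (4.03-fold), the chemokine receptor Ccr2 (3.79-fold), F13a1 (3.12-fold) and Gria3 (4.23-fold). Higher in MPP were Jchain (148-fold, 56.0 to 577), Vwf (51.1-fold, 23.1 to 142), Nrp2 (26.3-fold), Myo10, Shank3 and Ctsk, and 4 genes with 0 counts in LT-HSC: Synpo2 (95% interval from 65.4-fold), Siglech, a receptor of plasmacytoid dendritic cells (from 48.6-fold), Mmp14 (from 36.3-fold) and Src (from 32.98-fold). Igkc was 175-fold (104 to 321) and Ighm 13.7-fold (12.5 to 15.1) higher in MPP.

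Of 16 GMP markers, 13 were higher in LT-HSC and 0 lower, with a median log2 ratio of 0.50 above 100% of the random lists, led by Plac8 (2.31-fold), Ctsg (1.90-fold) and Nkg7 (1.73-fold). LT-HSC markers had 6 of 13 members lower in LT-HSC than in MPP and 0 higher (median -1.24, 0.10th percentile, or -1.67 with members at 0 set to their floor). Megakaryocyte and platelet markers were lower in 4 of 5 members (median -4.08, or -4.49 with members at 0 set to their floor), and stromal and endothelial markers in 5 of 6 (median -2.81, or -3.98). Large-subunit ribosomal proteins had 12 of 45 members higher and 1 lower (median 0.17, 99.2nd percentile), and proteasome subunits 12 of 37 higher and 2 lower (median 0.25). Of 30 lists, 15 lay outside the middle 95% of random lists. In all 116 of 4367 genes differed at least 2-fold, 44 higher and 72 lower in LT-HSC. These ratios compare the 2 libraries, not the 2 populations, and library totals lower the median of all genes by 0.11 on the log2 scale, which turns the small positive medians of erythroid markers, small-subunit and mitochondrial ribosomal proteins, initiation factors, synthetases and snoRNP proteins negative.

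GMP against MEP compares 2 branches of myeloid commitment, and the largest ratios were those of genes higher in MEP. In the library labelled MEP, Vwf was 180-fold (95% interval 51.7 to 1345) and Itga2b, the platelet integrin CD41, 113-fold (45.3 to 393) higher, and Pf4, platelet factor 4, had 62.4 CPM against 0 counts in GMP (95% interval from 19.1-fold). Kcnj5, Myom1, Dntt, Sdpr and Mrvi1 also had 0 counts in GMP (intervals from 16.99-fold to 19.9-fold at their lower ends), and H2-Ab1 was 36.1-fold higher in MEP. In the library labelled GMP, Mpo was 2.44-fold (2.35 to 2.54), Ms4a3 2.67-fold (2.16 to 3.32) and Cebpe, a transcription factor of granulocytes, 2.21-fold (1.87 to 2.61) higher. Ccnd1 was 5.08-fold, Tanc1 3.83-fold, Atp2b4 3.36-fold, Cdk5r1 4.28-fold and mt-Nd5 3.10-fold higher in GMP, followed by BC035044, Slc35a5, Prr11 and Ccl9.

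Of 16 GMP markers, 10 were higher in GMP and 1 lower (median 0.30, 97.54th percentile), and of 12 MEP markers 10 were lower and 0 higher (median -1.38, below 100% of random lists). Mature myeloid markers lay inside random lists (median 0.16, 78.9th percentile, 12 of 22 higher and 7 lower). Ribosome biogenesis factors had 14 of 36 members lower in GMP and 2 higher (median -0.50), with Utp20 (2.62-fold lower) and Noc2l (2.15-fold lower) among them, and aminoacyl-tRNA synthetases 8 of 20 lower and 0 higher (median -0.32). Immediate-early and heat-shock genes were lower in 11 of 13 (median -0.77), and mitochondrially encoded proteins higher in 6 of 7 (median 0.66). Cell cycle genes went both ways, 14 higher and 13 lower of 30, with the DNA replication genes Cdt1, Tyms, Mcm6 and Mcm4 lower by 4.96-fold, 3.74-fold, 3.33-fold and 2.39-fold. In all 314 of 4481 genes differed at least 2-fold, 130 higher and 184 lower in GMP. These ratios compare the 2 libraries only, and library totals, which lower the median of all genes by 0.20 on the log2 scale, gave 54 higher and 316 lower and turned the small positive medians of mature myeloid and erythroid markers, large- and small-subunit ribosomal proteins and the unfolded protein response negative.

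The question the series puts to its HSC groups is what loss of the snoRNA cluster changes in the translatome. B lineage genes were lower in the library labelled Mat-KO HSC than in WT HSC. In runs 1 and 2 the WT HSC library held 2588 heavy-chain V gene counts, 99.8% of them of Ighv1-47 alone, and Mat-KO HSC held 2. Whether the B lineage reads of WT HSC have to do with the genotype was not tested. Pax5, the B cell identity factor, was 26.8-fold lower (95% interval 9.38 to 122) and Ebf1 29.2-fold lower (6.99 to 357, on 3 counts). Jchain, Lef1, Akap12, Igll1 of the surrogate light chain, Dntt and Pou2af1 had 0 counts in Mat-KO, and the 95% intervals of their ratios begin at 20.1-fold, 10.7-fold, 10.6-fold, 10.4-fold, 8.86-fold and 7.93-fold lower. Cplx2 and Pgm2l1 were 15.9-fold and 19.2-fold lower. Higher in Mat-KO were the class II genes H2-Aa (13.6-fold, 8.18 to 24.0) and H2-Ab1 (8.99-fold, 5.36 to 15.7) with Cd74 (4.83-fold, 3.97 to 5.88), and Ypel4 (53.1-fold, 11.9 to 669, on 3 counts in WT), Tmcc2 (15.8-fold, 10.8 to 23.8), Ccdc130, Chst10, Cyp27a1, a sterol hydroxylase, Ms4a6b and the ubiquitin ligase Marchf3 (up to 12.7-fold). With LT-HSC as reference the class II genes turn, with H2-Aa at 167 CPM in Mat-KO and 288 CPM in LT-HSC, H2-Ab1 at 120 CPM and 264 CPM and Cd74 at 538 CPM and 618 CPM, and Cplx2 at 6.05 CPM and 5.89 CPM. Jchain and Dntt are low in LT-HSC too, at 1.65 CPM and 0.236 CPM. Pax5, by contrast, stayed 10.6-fold lower in Mat-KO than in LT-HSC (3.68 to 48.4), and Akap12, with 0 counts in Mat-KO, stood at 16.3 CPM in LT-HSC.

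Of 16 B cell markers, 13 were lower in Mat-KO and 1 higher (median log2 ratio -4.45, or -3.02 with 7 members at 0 set to their floor; below 100% of random lists), and 3 of 4 plasma cell markers were lower (median -4.53, or -2.86 at the floor). T cell markers (median -4.08, 3 members with 2 at 0) and CLP markers (-2.37, 9 members with 4 at 0) lay below the middle 95% of random lists as well, but their medians are -2.39 and -1.39 at the floor. In runs 1 and 2 alone they stood at the 3.79th and 32.8th percentiles, and CLP markers at the 36.4th in runs 3 and 4 alone and, with LT-HSC as reference, at a median of 0.16. Cell cycle genes were lower in 13 of 30 members and higher in 1 (median -0.44), with Mcm4 2.91-fold, Cenpf 2.17-fold, Rrm1 2.00-fold and Mki67 1.90-fold lower. Of 20 aminoacyl-tRNA synthetases 8 were lower and 1 higher (median -0.43, 0.15th percentile), with Nars 1.77-fold and Qars 1.73-fold lower, and of 37 proteasome subunits 4 were lower and 2 higher (median -0.33, 0.74th percentile, but the 10.57th in runs 1 and 2 alone and the 4.56th in runs 3 and 4 alone). GMP markers were higher in 9 of 16 and lower in 0 (median 0.37), led by Plac8 (2.38-fold) and Csf1r (2.17-fold). Against LT-HSC their direction turned (median -0.65, 2 higher and 10 lower). Myc was 3.04-fold higher (2.32 to 3.99) among MPP markers (median 0.50), and MEP markers (median 0.48), interferon response genes (0.41) and immediate-early genes (0.32), with Dusp1 2.25-fold and Egr1 1.91-fold higher, also lay above. The interferon response lay inside random lists in runs 1 and 2 alone (83.15th percentile) and in runs 3 and 4 alone (93.35th), and MEP (66.8th) and MPP markers (92.2nd) in runs 3 and 4 alone. Against LT-HSC, MPP markers lay inside them too (81.1st percentile). Against WT HSC the other lists of the translation machinery lay inside random lists: large-subunit ribosomal proteins had a median of -0.06 (3 of 44 higher, 3 lower), small-subunit ones -0.14 (0 higher and 4 lower of 32), initiation factors 0.04 (0 higher and 10 lower of 50), elongation and termination factors -0.06, mitochondrial ribosomal proteins -0.38 (-0.40 at the floor), ribosome biogenesis factors -0.16 and snoRNP proteins 0.06. Against LT-HSC, 5 of them lay below random lists in Mat-KO: large-subunit (median -0.41, 0.05th percentile), small-subunit (-0.57, below 100% of random lists) and mitochondrial ribosomal proteins (-0.64, 0.71st percentile), initiation factors (-0.34, 0.14th percentile) and elongation and termination factors (-0.48, 1.69th percentile). In all 12 of 28 lists lay outside the middle 95% of random lists. Chance gives 1.4 only if the members of a list vary independently, and the other comparisons of 2 libraries had 12 to 18 lists outside.

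**Figure D3:**
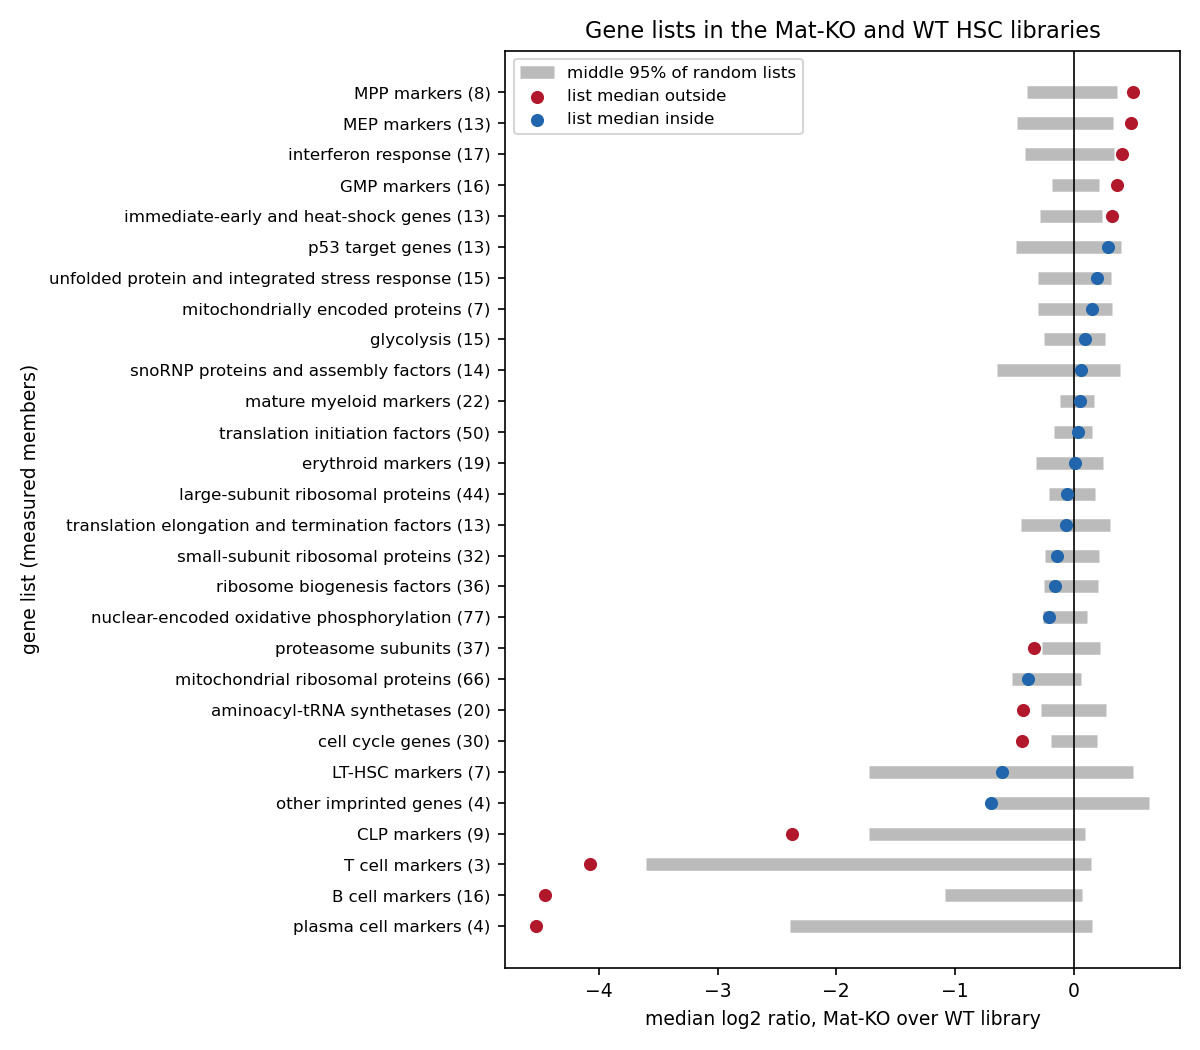
Median log2 ratio of Mat-KO over WT HSC (horizontal axis, 1 CPM added to both levels) for 28 gene lists (vertical axis, measured members in brackets), with grey bars for the middle 95% of 10000 random lists matched on level. B cell markers lie at -4.45, and large-subunit ribosomal proteins lie at -0.06, inside their bar.

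In all 320 of 4478 genes differed at least 2-fold, 157 higher and 163 lower in Mat-KO. LT-HSC, whose label gives no genotype, and WT HSC differed for 229 of 4440 genes, and 17 of 28 lists lay outside the middle 95% of random lists. In LT-HSC, GMP markers (median 1.08, 13 of 16 higher), large-subunit (0.47, 25 of 45 higher) and small-subunit ribosomal proteins (0.42, 15 of 32 higher) lay above random lists, and erythroid (-1.29, 17 of 19 lower), B cell (-1.02, 11 of 18 lower) and plasma cell markers (-2.11, 3 of 4 lower) below, so WT HSC stands high for B lineage genes against LT-HSC as well. Pax5 was nonetheless lower in Mat-KO than in LT-HSC too, at 6.05 CPM against 64.1 CPM. With all libraries thinned to the depth of Mat-KO, Mat-KO and WT differed for 339 genes and LT-HSC and WT for 292. The 55 pairs of libraries without Mat-KO differed for 105 to 605 genes (median 271), 14 of them for more than 339. The 11 pairs with Mat-KO differed for 339 to 710. These ratios compare the libraries, not the genotypes. The count was 544 with LT-HSC in place of WT HSC, 453 with runs 1 and 2 alone (170 higher and 283 lower), 132 with runs 3 and 4 alone (27 higher and 105 lower) and 209 without replicate 1 (79 higher and 130 lower). With the pairs of runs taken as 2 replicates, edgeR gave 237 such genes, 308 with a replicate block and 17 in a fit of the 2 groups alone, and DESeq2 43.

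**Figure D4:**
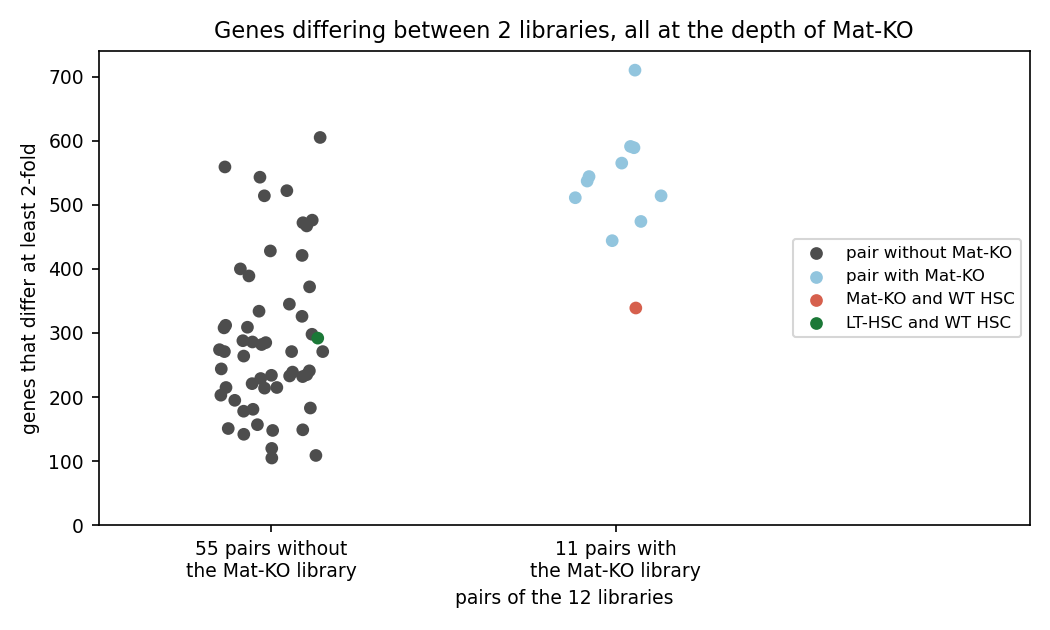
Number of genes that differ at least 2-fold (vertical axis) for each of the 66 pairs of the 12 libraries, thinned to 982124 counts, with 55 pairs without Mat-KO at the left and 11 pairs with it at the right. Mat-KO and WT HSC differ for 339 genes, and 14 of the 55 pairs at the left lie above them.

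The locus that carries the deletion was nearly empty of footprints. Between Meg3 and Mirg (mm10 chromosome 12, 109541001 to 109749460), runs 3 and 4 list 100 features, of which 10 had counts, 25 in all over the 12 libraries and at most 3 for one feature in one library. WT HSC had 0 counts there, where 3 counts would be 3.22 CPM, Mat-KO HSC 1 and LT-HSC 2. The 48 features of 65 to 80 bases had 3 counts together. Meg3 had 9 counts over the 12 libraries, Rian, the host transcript at 109603940 to 109661716, 4, Rtl1 4 and Mirg 1, and outside the region Dio3 had 29, Wdr25 62, Begain 5 and Dlk1 0. The 3 genes of the locus among the shared genes took at most 0.0011% of counts in any population. No loss or gain at the locus was detectable in these counts, and the genotype labels cannot be checked from it. Whether more depth would change this cannot be told. Footprints are fragments of mRNA, the cluster holds small nucleolar RNAs, and runs 3 and 4 had repeats and duplicates removed.

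Across the 8534 genes with a mean of 10 CPM or more, Pearson's r between libraries was 0.843 (GMP and Mat-KO HSC) to 0.947 (T cell and erythroid cell). The libraries labelled CLP and LT-HSC were each other's nearest (0.944), MPP (0.943), MEP (0.935) and myeloid cell (0.929) were nearest to CLP, and GMP (0.916) and CMP (0.930) to LT-HSC. T cell, B cell (0.933), WT HSC (0.927) and Mat-KO HSC (0.893) were nearest to erythroid cell. Over all genes WT HSC was nearest to CLP (0.960), CMP to CLP and GMP to CMP. Pearson's r over the 8534 genes between WT and Mat-KO HSC was 0.881, between LT-HSC and WT HSC 0.913 and between LT-HSC and Mat-KO HSC 0.871. The libraries were not thinned for this, and Mat-KO HSC held the fewest counts (982124). Its lower r cannot be told apart from an effect of depth. The first 3 principal components held 21.6%, 17.4% and 12.5% of the variance. These are correlations across genes, which are not independent replicates.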

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

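The tests of exchanged labels, of other marrow cells, of depth, of other library differences and of the run difference were chosen after the results were seen. The test of depth took the place of one that decided nothing, and its limit was set when its value was already known. Within the 6 stem and progenitor or the 4 mature libraries, 7 shares stood far from the others in 68 groups of values tested, where chance gives about 1 in 20.

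The library labelled GMP stood apart for translation lists, low in each: 0.497% of counts in initiation factors (others 0.610% to 0.646%), 0.133% in aminoacyl-tRNA synthetases (0.175% to 0.191%), 0.129% in mitochondrial ribosomal proteins (0.148% to 0.158%) and 0.0243% in snoRNP proteins (0.0437% to 0.0525%). Lars2 took 19.01% of its counts, the highest share of the 12, and its TMM factor of 0.910 was the lowest. The other stem and progenitor libraries had factors of 1.005 (LT-HSC) to 1.08 (MPP). On the TMM scale these gaps are therefore smaller, and whether GMP would still stand apart there was not tested. The library labelled MPP stood high for stromal and endothelial markers, at 0.0147% (others 0.00429% to 0.00703%), and CLP for NK cell markers, at 0.00415% (others up to 0.00111%). The library labelled T cell stood high for mitochondrially encoded proteins, at 0.275% (other mature libraries 0.108% to 0.126%). Outside the genes used here, a feature on chromosome 17 (39846958 to 39848788) took 36.4% to 62.2% of the counts of runs 3 and 4 and was not used here.

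The first pattern weighed is that the 9 marker lists of a population were not highest in the library of their label. An exchange of labels among the 12 libraries, as the only cause, is argued against for the T cell label. The library with most T cell markers at 50 CPM or more had 1 of 21. The same measure reached 8 of 18 for B cell markers in WT HSC, and 3 in the library labelled B cell. An exchanged library that also lacked the markers of its cells would give the same values, so an exchange itself is not excluded. No biological explanation was tested. Reads from other marrow cells may be in every library, although sorting by surface markers would remove such cells. In all 12, 22 of 22 mature myeloid markers stood at 50 CPM or more, with S100a9 at 5172 CPM or more. Whether such reads account for the pattern cannot be decided from this, since added reads do not by themselves take away the markers of the labelled cells. Whether these reads came from cells, from free RNA or from mixing between libraries stays open.

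The second pattern is the difference between the Mat-KO and WT HSC libraries. The lower depth of Mat-KO as the whole cause is argued against: with all libraries thinned to that depth, Mat-KO and WT differed for 339 genes, while another pair differed for 105. By this measure lower depth raised the count: thinning lowered it in 0 of 66 pairs. It took CLP and LT-HSC from 54 to 109 genes, and LT-HSC and WT HSC from 229 to 292. How much lower depth adds to the Mat-KO count stays open, since thinning does not copy the noise of preparing a shallow library. A difference between libraries unrelated to the deletion stays possible, but the pairs of libraries cannot decide it. Of the 55 pairs without Mat-KO, 14 differed for more genes, but these join libraries labelled as different populations. LT-HSC and WT HSC, at the same depth, differed for 292. Loss of the snoRNA cluster cannot be told apart from such a difference, because the locus held 0 counts in WT HSC and the runs of each genotype, which the submitters state as 2 biological replicates, were read as 1 sample.

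The third pattern is that runs 1 and 2 differ from runs 3 and 4 in every group. Separate sorts or animals are argued against in CMP, CLP, MPP and WT HSC: of 8 immunoglobulin chains with at least 100 and 50 counts of their leading V gene in the 2 pairs of runs, 8 had the same one in both, such as Ighv1-49 in CMP with 98.7% and 98.5% of heavy-chain V counts. The other groups, Mat-KO HSC among them, had too few such counts, and there it stays open. Read counting that differs by gene between the 2 kinds of file may account for most of it. Removing a factor per gene common to all groups cannot tell it from any other difference that all groups share. With that factor removed, the highest chi-square ratio, as a mean over genes, was 1.28. It was 0.456 within the pairs and up to 2.27 between the summed pairs, where summing runs that are not independent can by itself raise it. The cause of what remains stays open.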

How the results depend on the processing

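Totals without Lars2, equal depth, the factor per gene and single prefixes for lists were chosen after the results were seen. Of the alternative values of counts and other main values, 79 stayed within 1.5 times and 28 moved. Without a minimum level, the 2-fold counts were 1391 (Mat-KO against WT HSC), 1364 (LT-HSC against MPP), 1593 (GMP against MEP) and 6847 (each population against the other 9), where low counts enter by construction. Mat-KO against WT HSC gave 132 genes with runs 3 and 4 alone, 453 with runs 1 and 2 alone, 544 with LT-HSC as reference, 209 to 377 without one of the replicates, and, with the pairs of runs as 2 replicates, 17 in a fit of those 2 groups alone, 43 by DESeq2 and 308 with a replicate block. The other 2-fold counts held under every other alternative run.

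The count of 71 genes between stem and progenitor and mature libraries was 27 with library totals, 203 by DESeq2, 2 by limma-voom, 1578 with the pairs of runs as replicates of each population, 0 without the erythroid cell library and 0 to 304 without one of the others, and 60 to 84 without one replicate. Lists passing camera were 0 of 29 with an estimated correlation and 4 with library totals, against 11. Of the lists for Mat-KO against WT HSC, 7 rather than 12 lay outside random lists with runs 3 and 4 alone. The median of GMP markers reversed to -0.65 with LT-HSC as reference. Pearson's r between WT and Mat-KO HSC was 0.934 over all genes. The chi-square ratio of runs 1 and 3 fell from a median of 6.74 to a mean over genes of 1.17 with a factor per gene removed, as its construction allows. The cause of the other changes was not tested. With LT-HSC as reference for Mat-KO, the log2 ratio reversed for H2-Aa (-0.78), H2-Ab1 (-1.13), Cd74 (-0.20) and Cplx2 (0.0319). The log2 ratio of Mpo between GMP and MEP was 1.09 with library totals. Depth limits Mat-KO HSC most: 3 counts there are 3.02 CPM.

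Other splits of the 10 populations into 6 and 4 gave as many genes in 3 of 100 draws of the 210 possible, the real one included. The highest other split gave 116 genes, with the T cell, B cell, erythroid cell and MPP libraries as the 4.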

Other observations

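All values of this part but the list values were looked at after the results were seen, and no test was run for them. In several libraries 1 V gene led the immunoglobulin reads. In the library labelled CMP, Ighv1-49 made up 98.7% of heavy-chain V gene counts in runs 1 and 2 (3101 of 3143), in CLP Ighv9-1 made up 95.8% and Igkv4-50 99.7% of light-chain kappa V counts, and in WT HSC Ighv1-47 made up 99.8%. Ighg1, the heavy chain of a switched antibody, stood at 1425 CPM in WT HSC and at 1.07 CPM or less in each other library, while Ighm stood at 8163 CPM in CMP, 4741 CPM in CLP and 2791 CPM in MPP. In the library labelled B cell, Ighm stood at 92.2 CPM and Cd79a and Ebf1 had 0 counts.

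The library labelled myeloid cell was highest for 5 genes that macrophages express, Vcam1 at 765 CPM, Hmox1 at 416 CPM, Mrc1 at 316 CPM, Siglec1 at 189 CPM and C1qa at 99.7 CPM, and the library labelled B cell was second for Mrc1 (145 CPM) and Mat-KO HSC for Siglec1 (64.5 CPM). Siglech stood at 82.2 CPM in T cell and 79.6 CPM in MPP. Mki67 was highest in GMP, at 2115 CPM, and lowest in Mat-KO HSC, at 577 CPM. Among stem cell genes, Mecom had 0 counts in LT-HSC, Fgd5 and Procr had 0 counts there too, and Hlf stood at 5.66 CPM in LT-HSC and 20.1 CPM in myeloid cell. Xist had counts in each library, 18715 in total over runs 3 and 4 with at most 2495 in one, against at most 3 counts of Uty, 2 of Ddx3y and 1 of Kdm5d, the Y-linked genes read.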
